A study of Mus musculus with 8 samples.

How the data were processed

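Gene expression was measured in mouse primary hepatocytes from wild-type (WT) mice and from mice lacking transglutaminase 2 (KO), incubated for 15 h with 0 or 100 mM ethanol. Total RNA was extracted with RNeasy columns and turned into biotin-labelled cRNA by in vitro transcription, per the labels' protocols. Each of the 8 samples was hybridised to its own 1-colour Affymetrix array, which gave 2 arrays, A and B, in each of 4 groups.

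The deposited values are linear signal intensities, 1 per probe set and array, for 45101 probe sets including 64 control probe sets. The software, scanner settings and scaling that the authors used to summarise probes into these intensities are not given in the sources used here, and neither is a genome build. Detection calls were not used here. The unit was read from the values: array maxima lay between 14870 and 22940, and trimmed means (2% left out at each end) between 113.3 and 341.5, so the arrays had not been scaled to a common level. On the B array of ethanol-treated WT cells, 5410 values (12%) were unusable, of which 5403 were exact zeros and 7 impossible as intensities. They lay in 1 stretch of the table, among 1486 usable values, and the affected probe sets were left out, leaving 39627 complete ones.

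Groups were taken from the sample titles and source names. For the B arrays of both ethanol groups, the treatment text reads as an untreated incubation, although title and source name give 100 mM. The titles were followed, and 2 alternatives left these arrays out or counted them as untreated. Whether the 2 arrays of a group came from separate animals or cultures is not stated, so the p-values measure only the spread between these samples, which may be technical.

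Intensities were quantile normalised across the 8 arrays and transformed as log2(intensity + 16). A fold change on this scale understates the change of a dimly expressed gene. Tests were restricted to the 50% of probe sets with the highest mean, at or above 5.4 on the log2 scale, which left 19814. limma 3.58.1 in R 4.3.3 was fitted to all 8 arrays with 4 group means and an intensity trend in the variance prior, giving 4 residual and 5.43 prior degrees of freedom. Reported errors are the model's standard errors (SE) of log2 differences, and p-values were adjusted by the Benjamini-Hochberg method within each of 7 contrasts. A probe set was called at an adjusted p under 0.05. The contrasts were ethanol in WT, ethanol in KO, KO against WT untreated, KO against WT with ethanol, the difference between the ethanol effects (interaction), and the averaged effects of ethanol and genotype.

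Probe sets were named through the platform's annotation table, with symbols updated from the RefSeq gene table of GRCm38.p6. Of all probe sets, 34958 had 1 symbol, 932 several and 9211 none, and 34754 of the single symbols were matched to that table. Named results use the probe set of a gene with the highest mean over all arrays, and probe sets of a gene that were not called, or called the other way, are given with it. For each main contrast, the named genes were the 10 highest and 10 lowest log2 changes among called genes that moved the same way in A and B (5 and 5 for the averaged contrasts), up to 4 members of a described list with the smallest adjusted p, and a handful of genes chosen from the study's subject. Gene lists were tested with limma's camera, using a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated for each list. Of 34 lists, 29 had at least 5 tested members. Of the 685 genes on the lists, 624 were measured. The groups, contrasts, tests, filter, named-gene rule, gene lists and most alternatives were chosen before the data were examined.

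Arrays were assigned to 2 presumed hybridisation batches by the ratio of the bioC to the bioB spike-in control, split at 2. The batches were inferred from this ratio alone and not taken from the labels. Batch 1 held the A arrays of untreated WT, ethanol WT and ethanol KO. Batch 2 held the other 5 arrays. Since batch 1 has 1 array in each of 3 groups, it gives values without a test. Batch 2 has 2 arrays in untreated KO and 1 in each other group. Counts in batch 2 alone therefore rest on the spread of that 1 pair and do not check the main counts independently. The replicate letter was used as a block only as an alternative, because the labels do not say what A or B share. Other alternatives were an offset of 64 or none, no filter or the top 30% of probe sets, a variance prior without a trend, 1 probe set per gene, the compared groups alone, and leaving out each array in turn. Trimmed-mean scaling, keeping probe sets with a missing value, batch as a term, batch 2 alone, and leaving out dim arrays were added after the data were seen.

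The fit was tested on simulated data built from the 19814 real means and spreads with 200 changed probe sets per contrast. Noise was drawn independently for each probe set. For ethanol in WT, 14% of changes of 0.5, 54% of changes of 1 and 80% of changes of 2 on the log2 scale were recovered, with 3 false calls. For KO against WT untreated, the shares were 10, 46 and 78% with 5 false calls, and for the interaction 2, 16 and 56% with 1 false call. Of 30 simulated lists, the 1 that was moved was called and 0 others, which does not test lists whose genes vary together. In these simulations small changes, in particular of the interaction, were mostly missed. The real contrasts called 1061 to 8355 probe sets, far more than the 200 changed here. The simulated spread was also the same in every group, unlike that of the data. The recovered shares and false calls therefore need not hold for the real contrasts.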

Results

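Primary hepatocytes, the main metabolic cells of the liver, were isolated from WT and KO mice of a mixed C57BL6/129SVJ background and kept for 15 h without ethanol or with 100 mM ethanol. Transglutaminase 2, encoded by Tgm2, is an enzyme that crosslinks proteins, and the study concerns its action on the transcription factor Sp1 in liver injury. Each of the 4 groups had 2 arrays. Arrays of the same group correlated at 0.967 to 0.987 across probe sets and arrays of different groups at 0.918 to 0.982. Ethanol KO B correlated more with untreated KO A and B (0.973 and 0.972) than with ethanol KO A (0.967), and the second component, with 22.4% of the variance, held ethanol KO A at 63.54 and ethanol KO B at 8.241. The first principal component held 52.1% of the variance and separated WT arrays (27.23 to 50.02) from KO arrays (-52.17 to -24.59). Array brightness differed: trimmed means were 113.3 and 117 in untreated KO and 117.5 in ethanol KO A, against 228 to 341.5 on the other 5 arrays. The ratio of 3′ to 5′ signal rises as RNA is degraded or incompletely copied. For the control transcript Pcx it was 10 and 16.8 in untreated WT, 26.7 and 44.5 in ethanol WT, 10.6 and 8.69 in untreated KO, and 4.91 and 5.45 in ethanol KO. The log2 difference between A and B had an SD of 0.503 across probe sets in ethanol KO and of 0.315 to 0.327 in the other groups.

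**Figure D1:**
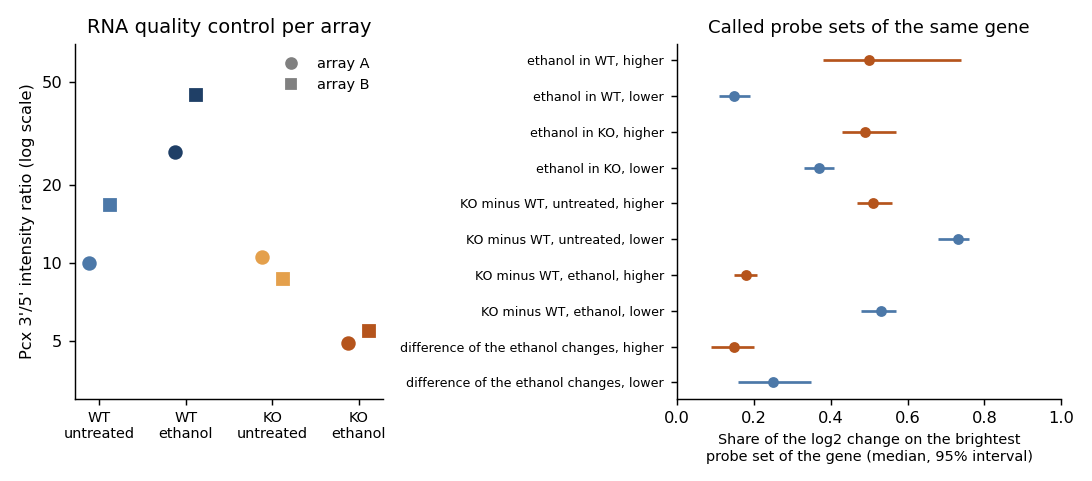
Left, Pcx 3′ to 5′ signal ratio on a log axis for each of the 8 arrays by group, highest in ethanol WT at 26.7 and 44.5. Right, median share (95% interval) of the log2 change of called probe sets that appears on the same gene's brightest probe set, by comparison and direction, lowest at 0.15 for probe sets lower with ethanol in WT and for those positive in the interaction.

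Tgm2 was measured first because it is the targeted gene. Its brightest probe set had a normalised intensity of 16700 to 16800 on the 4 WT arrays, at the top of the measured range, where quantile normalisation fixes the value. On the KO arrays it was 378 and 368 without ethanol and 704 and 628 with ethanol, or 2.25, 2.19, 4.19 and 3.74% of the WT mean. The KO minus WT difference was -5.43 ± 0.073 without ethanol (limma, adjusted p = 4.3e-10) and -4.63 ± 0.073 with ethanol (adjusted p = 2e-09, n = 2 arrays per group). Its size depends on the settings, with -5.25 and -4.46 under trimmed-mean scaling and -5.27 and -4.53 with an offset of 64. All 6 Tgm2 probe sets were lower in KO, by averaged log2 differences between -6.28 and -2.02. Which part of the gene was deleted is not given in the labels, so these probe sets need not lie in it. None of the 6 probe sets was called with ethanol in WT (0.00772 ± 0.073 on the brightest, adjusted p = 0.98). Normalisation fixes the brightest value in WT, so it cannot tell whether Tgm2 changed there. A dimmer probe set fell with ethanol in WT, from 7230 to 4860 on the A arrays and from 6710 to 4880 on the B arrays. Another rose (10800 to 11900 and 11100 to 11300), as did the dimmest (102 to 220 and 63.5 to 79.5). In KO, Tgm2 rose by 0.81 ± 0.073 on the brightest probe set (adjusted p = 0.00034), a call shared by 3 of the 6 probe sets. Tgm1, another transglutaminase, was higher in KO by 1.8 ± 0.1 without ethanol and 1.67 ± 0.1 with it (adjusted p = 4e-06 and 5.8e-06). Of the 4 transglutaminases tested, 2 were higher and 1 lower in untreated KO, the same counts as adjusted over the list alone.

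**Figure D2:**
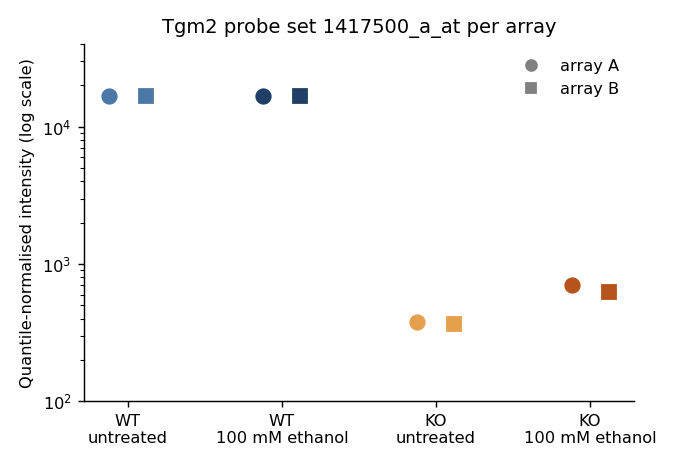
Normalised Tgm2 intensity on a log axis for each of the 8 arrays, by group. The 4 WT arrays lie at 16700 to 16800 and the 4 KO arrays at 368 to 704.

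Without ethanol, chemokine and other inflammatory genes were far higher in KO than in WT hepatocyte cultures (n = 2 arrays per group). Cxcl2, a neutrophil-attracting chemokine, was 46.5-fold higher (log2 5.54 ± 0.12, limma adjusted p = 8.6e-09), and the monocyte-attracting Ccl7 was 35.9-fold higher (5.16 ± 0.13, adjusted p = 1.7e-08). Ifi202b, an interferon-inducible gene of the p200 family, was 62-fold higher (5.95 ± 0.19, adjusted p = 7.1e-08). Il23a, a subunit of interleukin 23, rose by 5.6, Cxcl3 by 4.21, Nos2, the inducible nitric oxide synthase, by 3.91, and Serpinb2, an inhibitor of plasminogen activators, by 3.66. Rbm45 (4.2), the lipid droplet gene Cidea (3.92) and the niacin receptor Hcar2 (3.63) completed the 10 largest increases. Mean WT intensities of Ifi202b (2.81), Il23a (5.71) and Nos2 (2.51) lay below the offset of 16, so their differences depend on it. The same holds for Spsb4, Mapk13, Cyp17a1 and Osbpl5, which had KO means of 9.71, 11.2, 5.61 and 4.7. After Tgm2, the largest decreases were in Spsb4 (-3.92 ± 0.36), the stress-activated kinase gene Mapk13 (-3.07 ± 0.25) and Cyp17a1, a steroid hydroxylase (-2.95 ± 0.29). Tinagl1 (-2.79), Tcea3 (-2.75), Zfp593 (-2.72, on 1 of 2 probe sets), Epdr1 (-2.71), Spon2 (-2.71) and Osbpl5 (-2.67) followed. limma called 6394 of 19814 probe sets, 3036 higher and 3358 lower in KO, of which 1595 differed at least 2-fold.

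Of the fixed gene lists, NF-kB and chemokine genes were higher in untreated KO without exception, and interferon and hypoxia genes for the most part. All 19 tested genes of the NF-kB and chemokine list were higher, also when adjusted over the list alone, with a median of 2.6 and examples in Ccl2 (3.07) and Tnfaip3, a feedback inhibitor of NF-kB (3.5). Camera gave an adjusted p of 2.3e-20 for this list, and adjusted p = 0.014 with an estimated correlation. Of 23 interferon response genes, 17 were higher and 2 lower (19 and 2 adjusted over the list alone), with a median of 0.5, among them Ifit3 (1.41), Rsad2 (1.09) and Irf1 (1.16), and camera gave 7e-08 (adjusted p = 0.044 with an estimated correlation). Of 20 hypoxia and glycolysis genes, 12 were higher and 1 lower (the same adjusted over the list alone), with a median of 0.63, including the hypoxia-induced Adm (2.44) and Egln3 (2.43) and the glucose transporter gene Slc2a1 (1.29), and camera gave 1.4e-06 (adjusted p = 0.044 with an estimated correlation). Within batch 2, which had 2 KO arrays and 1 WT array, the 3 medians were 2.7, 0.51 and 0.64. Under trimmed-mean scaling the NF-kB and chemokine median was 3.04. The 2 untreated KO arrays were also dim. The 16 tested macrophage markers had a median difference of -0.045 without ethanol, with 1 higher and 3 lower (1 and 0 adjusted over the list alone). Averaged over both treatments, Cd68 was higher in KO by 1.56.

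Other lists moved less firmly in untreated KO. Acute phase genes were higher in 13 and lower in 4 of 24 cases (13 and 4 adjusted over the list alone), with Steap4 at 1.54, Il1rn at 2.08 and Crp, C-reactive protein, at 1.16, and camera gave 0.002 (adjusted p = 0.11 with an estimated correlation). The list median was 0.26, and 0.913 under trimmed-mean scaling. Cell cycle genes were lower in 11 and higher in 0 of 18 cases (11 and 0 adjusted over the list alone), with a median of -0.57, including the replication helicase genes Mcm7 (-0.765) and Mcm5 (-1.15), and camera gave 0.0034 (adjusted p = 0.12 with an estimated correlation). Of 26 proteasome genes, 16 were lower and 1 higher (17 and 2 adjusted over the list alone), with Psmc5 at -0.838 and Psmb3 at -0.618, and camera gave 0.003 (adjusted p = 0.31 with an estimated correlation). Amino acid, urea and gluconeogenesis genes were lower in 14 and higher in 5 of 23 cases (14 and 5 adjusted over the list alone), with Bhmt, which remethylates homocysteine, at -1 and pyruvate carboxylase Pcx at -0.999, and camera gave 0.037 (adjusted p = 0.31 with an estimated correlation). Trimmed-mean scaling ended the proteasome call (adjusted p = 0.34) and the amino acid call (0.19), which also ended with the B ethanol arrays counted as untreated (0.25), the top 30% filter (0.081) and no variance trend (0.095). Within batch 2 the medians of the 4 lists were 0.25, -0.63, -0.3 and -0.38. The count of 6394 fell to 3972 without untreated WT A, 4016 without untreated KO A, 4078 without untreated KO B and 4197 without untreated WT B. It was 6242 with batch as a term, while batch 2 alone holds 1 untreated WT array and gives no spread within WT.

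**Figure D3:**
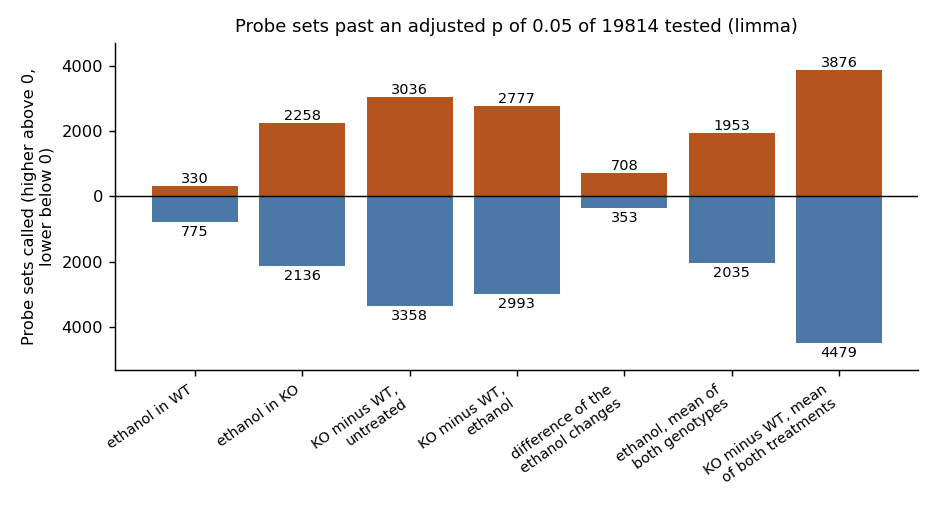
Number of probe sets called higher and lower by limma in each contrast, out of 19814 tested. The 2 comparisons of KO with WT called 6394 and 5770, ethanol called 4394 in KO and 1105 in WT, and the interaction called 1061.

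With ethanol present, the same comparison again showed chemokine genes higher in KO (n = 2 arrays per group). Cxcl2 was 38.3-fold higher (5.26 ± 0.12, limma adjusted p = 1.7e-08), Ccl7 19.7-fold (4.3 ± 0.13, adjusted p = 7.4e-08) and Cxcl1 13.4-fold (3.74 ± 0.11, adjusted p = 7.4e-08). Ccl2, a monocyte chemoattractant, was 9.8-fold higher (3.29 ± 0.063, adjusted p = 6.3e-09). Ifi202b (5.02), the protease gene Ctse (3.71, on 1 of 2 probe sets), Cidea (3.38), Il23a (3.33), Rbm45 (3.25) and Ivl, a transglutaminase substrate of the epidermal envelope (3.09), were also raised. Tgm2 (-4.63), Spsb4 (-3.78), Mapk13 (-3.13), Tcf24 (-2.89), Zfp593 (-2.87, on 1 of 2 probe sets), Epdr1 (-2.6), Smpdl3b (-2.59), Cyp39a1, which hydroxylates oxysterols (-2.52), Wtip (-2.49) and Ctsw (-2.48) had the largest decreases. Ethanol WT means of Ctse (2.55) and Ifi202b (2.29) and ethanol KO means of Mapk13 (5.34), Smpdl3b (8.61) and Ctsw (9.35) lay below the offset, so these differences depend on it. limma called 5770 probe sets, 2777 higher and 2993 lower, with 1510 changed at least 2-fold. The balance between directions was not stable: it was 3108 and 2725 under trimmed-mean scaling, 3142 and 1782 with probe sets missing on 1 array kept, 1784 and 1599 without ethanol WT A, and 1875 and 1431 without ethanol WT B.

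Of the 19 NF-kB and chemokine genes, 17 were higher and 0 lower in ethanol KO (19 and 0 adjusted over the list alone), with a median of 2. Camera gave 1.5e-20 (adjusted p = 0.013 with an estimated correlation). Hypoxia and glycolysis genes were higher in 16 and lower in 0 of 20 cases (16 and 0 adjusted over the list alone), with a median of 0.78, Egln3 at 2.08, Adm at 2.01 and Vegfa, the vascular growth factor, at 1.93. The list test, camera, gave 7.1e-13 (adjusted p = 0.017 with an estimated correlation). Of 23 interferon response genes 10 were higher and 0 lower (10 and 0 adjusted over the list alone), with Ifit3 at 1.16 and Oasl1 at 1.03, and camera gave 1.2e-05 (adjusted p = 0.086 with an estimated correlation). Proteasome genes were lower in 15 and higher in 0 of 26 cases (17 and 0 adjusted over the list alone), with Psmb3 at -0.552 and Psmc3 at -0.566, and camera gave 1.2e-05 (adjusted p = 0.17 with an estimated correlation). Cell cycle genes were lower in 11 of 18 cases and higher in 0 (11 and 0 adjusted over the list alone), with Mcm5 at -1.83 and Mcm6 at -0.807, and camera gave 0.00072 (adjusted p = 0.1 with an estimated correlation). Within batch 1 the medians of these 5 lists were 2.2, 0.83, 0.44, -0.25 and -0.68, and within batch 2 they were 1.8, 0.7, 0.3, -0.27 and -0.65. All 19 NF-kB and chemokine genes were above 0 in both batches, and ethanol KO B, which paired with ethanol WT B in batch 2, was not a dim array.

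Acute phase genes were higher in 8 and lower in 3 of 24 cases in ethanol KO (9 and 4 adjusted over the list alone), with Lcn2 at 0.838 and Apcs at -0.781, and camera gave 0.0041 (adjusted p = 0.12 with an estimated correlation). Lipogenesis genes were higher in 10 and lower in 4 of 20 cases (10 and 4 adjusted over the list alone), with Elovl5 at 0.987, Me1 at 1.01, fatty acid synthase Fasn at 0.801 and Gpam at -0.822, and camera gave 0.009 (adjusted p = 0.17 with an estimated correlation). Fatty acid oxidation genes and PPARa targets went both ways, 8 higher and 6 lower of 29 (9 and 6 adjusted over the list alone), with Cyp4a12a at 2.29 and Cyp4a14 at -2.15, and camera gave 0.033 (adjusted p = 0.19 with an estimated correlation). Within batches 1 and 2 the medians were 0.14 and 0.12, 0.39 and 0.31, and 0.2 and 0.092. The fatty acid oxidation call ended without ethanol KO A (0.063), without a variance trend (0.067), without the 3 dim KO arrays (0.075) and under trimmed-mean scaling (0.18), which also ended the lipogenesis call (0.074), gave medians of 0.222 for acute phase and 0.505 for interferon genes, and moved the median of all probe sets in this contrast by 0.11. The Pcx 3′ to 5′ ratio was 26.7 and 44.5 in ethanol WT and 4.91 and 5.45 in ethanol KO. Probe sets called higher in KO showed a median share of 0.18 (0.15 to 0.21) of their change on the gene's brightest probe set, over 1221 probe sets. The count of 5770 was 3306 without ethanol WT B, 3383 without ethanol WT A, 4990 without the 3 dim KO arrays, 6597 with batch as a term, 4482 in batch 2 alone, and 1367 with the B ethanol arrays counted as untreated, which ended the lipogenesis call (0.077).

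**Figure D4:**
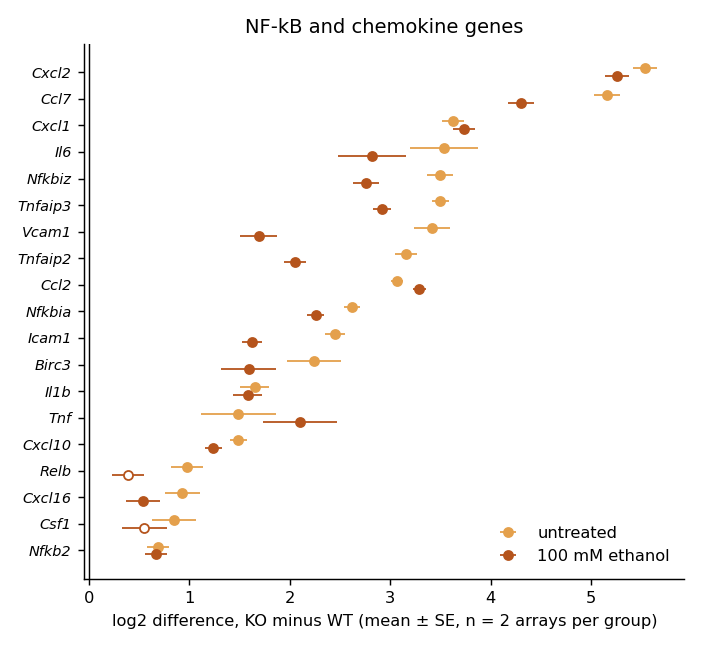
KO minus WT log2 difference of each of the 19 tested NF-kB and chemokine genes, without and with ethanol. Filled points are called, bars are the SE, and the medians are 2.6 without ethanol and 2 with ethanol.

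In WT hepatocytes, 100 mM ethanol for 15 h raised Gm13889, G6pc and Ddit3 and lowered Ivl, Cyp26a1 and Thbs1 (n = 2 arrays per group). Gm13889 rose by 2.14 ± 0.15 (limma adjusted p = 0.00015) and G6pc, the glucose-6-phosphatase of glucose release, by 1.41 ± 0.21 (adjusted p = 0.0052). Ddit3, a stress-induced transcription factor, rose by 1.12 ± 0.15 (adjusted p = 0.003), and Cyp2b10, a drug-metabolising enzyme, by 1.08 ± 0.1 (adjusted p = 0.00063). The mitochondrial carrier gene Slc25a47 rose by 1.12 ± 0.088 (adjusted p = 0.00028). Lhfpl2 (1.51), Slco2b1 (1.15), Sdr42e1 (1.13), Apol7a (1.12) and the hepatocyte transcription factor Cebpa (1.05) were also among the 10 largest increases. Ivl fell by 3.02 (SE 0.1, adjusted p = 2.2e-06), Cyp26a1, which degrades retinoic acid, by 2.3 (SE 0.11, adjusted p = 2.6e-05) and Thbs1, a matrix glycoprotein, by 2.11 (SE 0.14, adjusted p = 0.00011). Ctse (-2.21), Cnnm4 (-1.63), the prostaglandin synthase gene Ptgs2 (-1.4), Habp2 (-1.36), Lmcd1 (-1.32), Net1 (-1.31) and Tnfrsf23 (-1.27) were also lower. Cnnm4 was called on 1 of 3 probe sets and Lhfpl2, Ctse, Ptgs2 and Habp2 on 1 of 2. limma called 1105 probe sets, 330 higher and 775 lower. Leaving out 1 array ended the call of Apol7a for 6 of the 8 arrays (adjusted p up to 0.26, without untreated WT A), of Lhfpl2 for 4 (up to 0.16, without ethanol WT B), of Cebpa for 4 (up to 0.081, without ethanol WT B), of Ptgs2 for 3 (up to 0.093, without untreated WT B) and of G6pc for 2 (up to 0.066, without ethanol WT A).

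Among the lists, 8 of 20 hypoxia and glycolysis genes fell and 0 rose with ethanol in WT (10 and 0 adjusted over the list alone), with a median of -0.28, Bnip3 at -0.622, Pgam1 at -0.466 and pyruvate kinase Pkm at -0.605. Camera gave 8.8e-11 (adjusted p = 0.046 with an estimated correlation). ER stress and integrated stress response genes rose in 5 and fell in 0 of 30 cases (15 and 2 adjusted over the list alone), with a median of 0.3, and included the chaperone genes Hyou1 (0.774) and Hspa5 (0.255), and camera gave 0.00067 (adjusted p = 0.14 with an estimated correlation). Of 22 TGFb, matrix and cytoskeleton genes 3 fell and 0 rose (6 and 1 adjusted over the list alone), namely Thbs1, Ccn2 (-0.561) and Itgb1 (-0.576), and camera gave 0.005 (adjusted p = 0.18 with an estimated correlation). The proteasome list had 1 gene higher and 0 lower of 26 (0 and 0 adjusted over the list alone), Psmc3 at 0.308, and camera gave 0.0087 (adjusted p = 0.41 with an estimated correlation). Within batches 1 and 2 the medians were -0.37 and -0.23, 0.28 and 0.25, -0.12 and -0.074, and 0.11 and 0.11. Of 19 NF-kB and chemokine genes 4 fell and 1 rose (4 and 1 adjusted over the list alone), with Ccl2 at -0.652 and Icam1 at 0.515, and camera gave 0.13.

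Genes of bile acid synthesis and transport rose in 2 and fell in 0 of 16 cases in WT (6 and 1 adjusted over the list alone), namely the bile salt export pump gene Abcb11 (0.745) and Slco1b2 (0.483), and camera gave 0.02 (adjusted p = 0.41 with an estimated correlation). Fatty acid oxidation genes and PPARa targets rose in 3 and fell in 1 of 29 cases (7 and 1 adjusted over the list alone), with Creb3l3 at 0.628 and Cpt1a, which carries fatty acids towards mitochondria, at 0.589, and camera gave 0.023 (adjusted p = 0.3 with an estimated correlation). Hepatocyte identity and plasma protein genes rose in 2 and fell in 0 of 22 cases (2 and 0 adjusted over the list alone), Cebpa (1.05) and Hnf4a (0.462), and camera gave 0.042 (adjusted p = 0.41 with an estimated correlation). Within batches 1 and 2 the medians were 0.39 and 0.23, 0.19 and 0.22, and 0.084 and 0.081. The hepatocyte identity call ended without untreated WT A (0.068), ethanol WT A (0.088) or untreated WT B (0.074), and under trimmed-mean scaling (0.076). The bile acid call ended without ethanol WT A (0.075) or untreated WT B (0.054), and the fatty acid oxidation call without untreated WT B (0.054). With the top 30% filter the bile acid, fatty acid oxidation and hepatocyte identity calls ended (0.12, 0.12 and 0.15), and without a variance trend the last 2 (0.054 and 0.12) and the proteasome call (0.083).

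The 3′ to 5′ ratios of the WT arrays rose with ethanol. The Pcx 3′ to 5′ ratio was 10 and 16.8 without ethanol and 26.7 and 44.5 with it, and that of Actb was 1.62 and 1.48 in ethanol WT against 1.15 to 1.33 on the other arrays. That of Gapdh went from 0.831 and 0.821 to 0.977 and 0.928. Pcx was itself called lower in untreated KO and higher with ethanol in KO, so its ratio alone does not settle RNA quality. Probe sets that fell in WT showed a median share of 0.15 (0.11 to 0.19) of their change on the gene's brightest probe set, over 448 probe sets, and those that rose a share of 0.5 (0.38 to 0.74) over 63. With 1 probe set per gene 523 genes were called, of which 48.2% rose, against 29.9% of the 1105 probe sets. With 1 array left out the count was 284 (untreated WT B), 304 (ethanol WT A), 313 (untreated WT A), 391 (ethanol WT B), 585 (untreated KO B), 590 (untreated KO A), 2081 (ethanol KO B) and 2088 (ethanol KO A). With batch as a term 1439 probe sets were called, and in batch 2 alone 650. With the B ethanol arrays counted as untreated limma called 0, with 752 at an unadjusted p under 0.05, and the ER stress, TGFb, proteasome, bile acid, fatty acid oxidation and hepatocyte identity calls ended (adjusted p of 0.13, 0.18, 0.35, 0.084, 0.35 and 0.29).

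In KO hepatocytes, ethanol lowered Serpinb2, Cxcl3 and Nos2 and raised Slc25a47, Apoa5 and G6pc (n = 2 arrays per group). Serpinb2 fell by 3.17 (SE 0.37, limma adjusted p = 0.00078), Cxcl3 by 2.96 (SE 0.3, adjusted p = 5e-04) and Nos2 by 1.84 (SE 0.3, adjusted p = 0.0031). Thbs1 fell by 2.14 (SE 0.14, adjusted p = 8.9e-05). The chemokine receptor gene Ackr3 (-2.23), Mmp24 (-2.12), AA467197 (-2.01), the serotonin receptor gene Htr2b (-1.96), the collagenase gene Mmp13 (-1.96) and Yod1 (-1.83) were also lower. Slc25a47 rose by 2.2 ± 0.088 and Apoa5, an apolipoprotein of triglyceride metabolism, by 1.82 ± 0.072 (adjusted p = 5.9e-06 for both). Tcl1b3 rose by 2.74 ± 0.25 (adjusted p = 0.00034), G6pc by 2.23 ± 0.21 (adjusted p = 0.00038) and the liver transcription factor Foxa2 by 1.77 ± 0.19 (adjusted p = 0.00054). Hdac11 (1.97), Ccdc180 (1.89), Gprin3 (1.82), Cnnm1 (1.76) and Faim2 (1.76) completed the 10 largest increases. Hdac11 and Mmp24 were called on 1 of 2 probe sets. limma called 4394 probe sets, 2258 higher and 2136 lower. Leaving out 1 array ended the call of Htr2b and of Yod1 for 3 arrays, of Mmp24 and of Cnnm1 for 2 and of Hdac11 for 1, with adjusted p up to 0.098, 0.092, 0.06, 0.1 and 0.074, each without untreated KO B.

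Of 19 NF-kB and chemokine genes, 9 fell and 0 rose in KO (13 and 0 adjusted over the list alone), with a median of -0.43, Tnfaip3 at -0.976, the adhesion gene Vcam1 at -1.66 and Ccl7 at -1.14. The list test, camera, gave 3.9e-06 (adjusted p = 0.13 with an estimated correlation). Amino acid, urea and gluconeogenesis genes rose in 13 and fell in 1 of 23 cases (13 and 2 adjusted over the list alone), with a median of 0.41, Pcx at 0.65 and Fah at 0.506, and camera gave 0.00014 (adjusted p = 0.18 with an estimated correlation). ER stress genes rose in 15 and fell in 2 of 30 cases (18 and 2 adjusted over the list alone), with Chac1 at 1.18, Trib3 at 0.885 and Ddit3 at 1.02, and camera gave 0.001 (adjusted p = 0.17 with an estimated correlation). Hypoxia and glycolysis genes fell in 8 and rose in 1 of 20 cases (11 and 1 adjusted over the list alone), with Ndrg1 at -0.796 and Aldoa at 0.357, and camera gave 0.0085 (adjusted p = 0.18 with an estimated correlation). Fatty acid oxidation genes rose in 10 and fell in 1 of 29 cases (11 and 1 adjusted over the list alone), with Cpt2 at 0.778 and Acads at 0.724, and camera gave 0.024 (adjusted p = 0.23 with an estimated correlation). Within batch 2, with 1 ethanol array and 2 untreated arrays, the medians of these 5 lists were -0.67, 0.39, 0.33, -0.22 and 0.17. The fatty acid oxidation call ended without untreated KO B (0.057) or ethanol KO B (0.061), and the hypoxia call without ethanol KO B (0.061). Trimmed-mean scaling gave a median of -0.789 for the NF-kB and chemokine list and ended the ER stress (0.09), amino acid (0.052) and fatty acid oxidation (0.43) calls. The fatty acid oxidation call also ended with the top 30% filter (0.059), without a variance trend (0.07) and without both B ethanol arrays (0.053), which ended the hypoxia call as well (0.053).

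The Pcx 3′ to 5′ ratio was 10.6 and 8.69 in untreated KO and 4.91 and 5.45 in ethanol KO, whereas that of Gapdh went from 0.78 and 0.771 to 0.826 and 0.839 and that of Actb from 1.25 and 1.24 to 1.23 and 1.15. Ethanol KO B was the only bright KO array. Probe sets that fell in KO showed a median share of 0.37 (0.33 to 0.41) of their change on the gene's brightest probe set, and those that rose a share of 0.49 (0.43 to 0.57). The count of 4394 was 1642 without untreated KO A, 1706 without untreated KO B and 7479 without ethanol KO B (3497 higher and 3982 lower). It was 3851 with batch as a term, 3433 in batch 2 alone, 2441 with the KO groups fitted alone (1511 for ethanol in WT with the WT groups alone), 2682 without a trend in the variance prior and 380 with the B ethanol arrays counted as untreated. Counting them so ended all 5 list calls (adjusted p of 0.15, 0.15, 0.37, 0.57 and 0.39, in the order given).

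Whether ethanol acts differently without transglutaminase 2 was tested as the interaction, the ethanol change in KO minus that in WT (n = 2 arrays per group). Tcl1b3 had a difference of 2.86 ± 0.35 (limma adjusted p = 0.0038), Ctse of 2.79 ± 0.31 (adjusted p = 0.0025), the transcription factor gene Klf3 of 2.12 ± 0.21 (adjusted p = 0.0018) and the magnesium transport gene Cnnm4 of 2.02 ± 0.25 (adjusted p = 0.0039). E2f5, Faim2, Ccdc180, 4931429L15Rik, Zfp618 and Habp2 had differences of 2.19, 2.19, 1.94, 1.93, 1.79 and 1.76. Serpinb2 (-2.4), Il23a (-2.28), Cxcl3 (-2.1), Irak1, a kinase of interleukin 1 signalling (-1.87), Nos2 (-1.87), Mxd1 (-1.83), Ackr3 (-1.77), Vcam1 (-1.73), Swt1 (-1.49) and Sephs2 (-1.44) had the most negative differences. Mean WT intensities were 2.51 and 2.93 for Nos2 without and with ethanol, and 19.9 and 5.06 for Serpinb2, so these differences mainly restate the fall in KO. The means of Ctse in ethanol WT (2.55), of Zfp618 and Faim2 in untreated KO (1.25 and 9.43) and of Mxd1 in untreated WT (9.87) also lay below the offset, on which their differences depend. Il23a had a change of 1.05 ± 0.28 in WT (adjusted p = 0.065, mean intensities 5.71 and 29.6) and of -1.23 ± 0.28 in KO (adjusted p = 0.014). For Ctse, E2f5, Klf3, Cnnm4, Habp2, Irak1, Swt1 and Sephs2, 1 of the 2 to 4 tested probe sets was called. Of 19 NF-kB and chemokine genes, 5 had a negative and 0 a positive difference (7 and 0 adjusted over the list alone), including Tnfaip2 (-1.11) and Icam1 (-0.831), with a median of -0.4, and camera gave 0.00072 (adjusted p = 0.29 with an estimated correlation). Of 23 amino acid, urea and gluconeogenesis genes, 5 had a positive and 0 a negative difference (10 and 0 adjusted over the list alone), including Got1 (0.942) and Mat1a (0.509), with a median of 0.3, and camera gave 0.01 (adjusted p = 0.54 with an estimated correlation). The amino acid call was at 0.05 without untreated WT B and ended under trimmed-mean scaling (0.64) and without a variance trend (0.051).

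limma called 1061 probe sets in the interaction, 708 positive and 353 negative, and this balance was not kept without ethanol KO B (2105 and 2275) or without both B ethanol arrays (1607 and 1654). They showed a median share of 0.17 (0.13 to 0.21) of their change on the gene's brightest probe set, over 450 probe sets, while 5.74% of genes were called with 1 probe set per gene against 5.35% of all probe sets. The Pcx ratio rose with ethanol in WT (10 and 16.8 to 26.7 and 44.5) and fell in KO (10.6 and 8.69 to 4.91 and 5.45). That of Gapdh rose in both, from 0.831 and 0.821 to 0.977 and 0.928 in WT and from 0.78 and 0.771 to 0.826 and 0.839 in KO. Leaving out 1 array ended the call of E2f5, Faim2, Ccdc180, 4931429L15Rik, Zfp618, Serpinb2, Il23a, Cxcl3, Irak1, Nos2, Mxd1, Ackr3, Vcam1 and Swt1 for 1 to 7 of the 8 arrays, with adjusted p up to 0.18 (Nos2, without untreated KO B). Tcl1b3, Ctse, Klf3, Cnnm4, Habp2 and Sephs2 were called whichever array was left out. The count was 199 without untreated KO A, 248 without untreated KO B, 297 without untreated WT A, 323 without untreated WT B, 331 without ethanol WT A, 330 without ethanol WT B and 4380 without ethanol KO B. It was 1066 with batch as a term, 684 in batch 2 alone and 85 without a trend in the variance prior. With the B ethanol arrays counted as untreated limma called 0, with 2401 at an unadjusted p under 0.05, and both list calls ended (adjusted p = 0.51 for each).

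Across the 19814 probe sets the ethanol changes in WT and KO, which share no array, correlated at r = 0.211 (Spearman 0.226), and genes are not independent replicates. Of the probe sets that rose in WT, 193 also rose in KO, where independent lists would share 37.6, and of those that fell 306 also fell, against 83.5. Opposite calls numbered 14 and 72, against 35.6 and 88.3 for independent lists. The correlation was 0.242 with batch as a term and 0.234 in batch 2 alone. Without untreated WT B it was 0.122, the lowest value with 1 array left out.

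**Figure D5:**
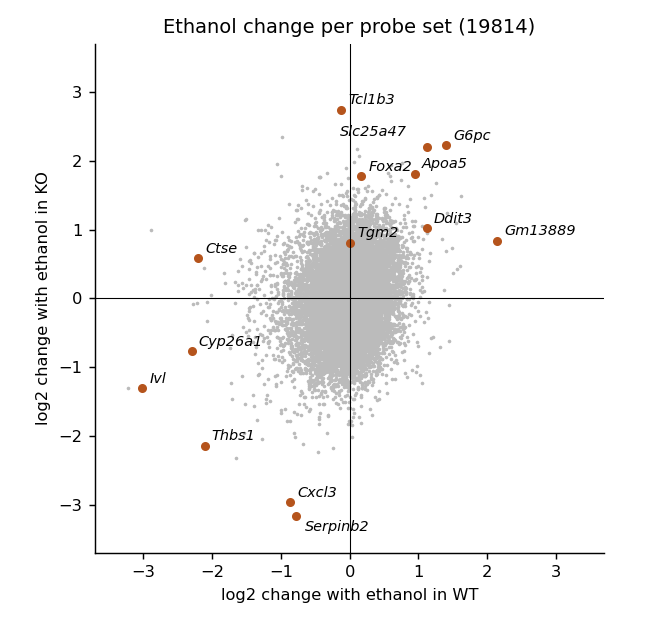
Ethanol log2 change in KO against that in WT for the 19814 tested probe sets, 1 grey point each, with 14 named genes in colour. The correlation across probe sets is 0.211, with Tcl1b3 and Serpinb2 changed in KO and Ivl and Cyp26a1 lowest in WT.

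Genes tied to the study's subject were followed in all comparisons. Sp1 was higher in untreated KO by 0.546 ± 0.11 (limma adjusted p = 0.0046, n = 2 arrays per group), called on 1 of 2 probe sets, and was not called between KO and WT with ethanol (0.19 ± 0.11, adjusted p = 0.23) or with ethanol in WT (0.248 ± 0.11, adjusted p = 0.26) or KO (-0.107 ± 0.11, adjusted p = 0.52). Of 15 genes in the list of Sp1 relatives and textbook Sp1-driven genes, 6 were higher and 4 lower in untreated KO (6 and 4 adjusted over the list alone), and camera gave 0.38. Met, the hepatocyte growth factor receptor, was lower in KO (-0.502 ± 0.082 without ethanol and -0.611 ± 0.082 with it, adjusted p = 0.0015 and 0.00061), but its other probe set was called in the opposite direction with ethanol. Ethanol left the brighter Met probe set at -0.0095 ± 0.082 in WT (adjusted p = 0.98), while the dimmer Met probe set fell by 1.29 (-1.29 ± 0.18, adjusted p = 0.0041). Egfr, the epidermal growth factor receptor, rose with ethanol in KO by 0.555 ± 0.13 (adjusted p = 0.015) on its brightest probe set, while 2 of its 6 probe sets were called lower. It was 0.399 ± 0.13 higher in KO than in WT with ethanol (adjusted p = 0.044), a call that ended for 7 of the 8 arrays left out in turn (up to 0.26, without ethanol WT B), and the rise in KO ended for 3 (up to 0.088, without untreated KO A). Cyp2e1, an ethanol-oxidising enzyme, was higher in KO by 0.6 ± 0.082 without and 0.639 ± 0.082 with ethanol (adjusted p = 0.00056 and 0.00045). Ethanol left it at -0.0608 ± 0.082 in WT and -0.0211 ± 0.082 in KO (adjusted p = 0.79 and 0.88). The alcohol and aldehyde dehydrogenase genes Adh1 and Aldh2 were not called in any of these comparisons on their brightest probe sets, with ethanol changes in WT of 0.119 ± 0.058 and 0.171 ± 0.1 (adjusted p = 0.32 and 0.43).

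Averaged over genotypes, ethanol changed 3988 probe sets by limma's test, led upwards by G6pc (1.82 ± 0.15), Slc25a47 (1.66 ± 0.062), Cphx3 (1.55 ± 0.33), Gm13889 (1.49 ± 0.1) and Apoa5 (1.38 ± 0.051). Ivl (-2.16 ± 0.071), Thbs1 (-2.12 ± 0.097), Serpinb2 (-1.97 ± 0.26), Cxcl3 (-1.92 ± 0.21) and Htr2b (-1.75 ± 0.32) led downwards. The count was 2213 without untreated KO B, 2236 without untreated KO A, 2391 without untreated WT A, 2400 without untreated WT B, 2412 without ethanol WT A, 2484 without ethanol WT B and 6550 without ethanol KO B. It was 4051 with batch as a term, 2979 in batch 2 alone, and 2 with the B ethanol arrays counted as untreated. Averaged over treatments, 8355 probe sets differed between KO and WT, with Ifi202b (5.49 ± 0.13), Cxcl2 (5.4 ± 0.086), Ccl7 (4.73 ± 0.09), Il23a (4.47 ± 0.2) and Rbm45 (3.73 ± 0.19) highest and Tgm2 (-5.03 ± 0.051), Spsb4 (-3.85 ± 0.26), Mapk13 (-3.1 ± 0.18), Zfp593 (-2.8 ± 0.076) and Epdr1 (-2.66 ± 0.17) lowest. This count was 8893 with batch as a term and 7741 in batch 2 alone.

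Some lists were called only in the averages. With ethanol, cytochrome P450 genes of drug metabolism were higher in 5 and lower in 0 of 20 cases (5 and 0 adjusted over the list alone), and camera gave 0.041 (adjusted p = 0.24 with an estimated correlation). Heat shock genes were higher in 7 and lower in 0 of 16 cases (7 and 0 adjusted over the list alone), and camera gave 0.035 (adjusted p = 0.35 with an estimated correlation). Trimmed-mean scaling ended both calls (0.82 and 0.72), as did counting the B ethanol arrays as untreated (0.38 and 0.56). Between genotypes, ethanol and aldehyde metabolism genes were higher in KO in 8 and lower in 3 of 14 cases (8 and 3 adjusted over the list alone), and camera gave 0.04 (adjusted p = 0.32 with an estimated correlation). Mitochondrial respiratory chain genes were lower in 12 and higher in 2 of 30 cases (12 and 2 adjusted over the list alone), and camera gave 0.04 (adjusted p = 0.31 with an estimated correlation, 0.23 under trimmed-mean scaling and 0.14 with the B ethanol arrays counted as untreated). Leaving out 1 array ended the cytochrome P450 call for ethanol KO B (0.11) and 4 others, the heat shock call for untreated WT A (0.057), the aldehyde call for ethanol KO B (0.073) and untreated KO A (0.054), which batch as a term (0.052), no variance trend (0.057) and leaving out both B ethanol arrays (0.07) also ended, and the respiratory chain call for untreated KO A (0.07). The top 30% filter ended the cytochrome P450, heat shock and respiratory chain calls (0.13, 0.099 and 0.07), as did a prior without a variance trend (0.08, 0.078 and 0.12). Without both B ethanol arrays the first 2 of these ended (0.077 and 0.072), and without the filter the cytochrome P450 call (0.067).

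Markers of other cell types were compared between KO and WT over both treatments without the filter. The 17 measured macrophage markers had a median of -0.067, with the lysosomal Cd68 higher (1.56 ± 0.067, limma adjusted p = 3.4e-07), Ctss higher (0.398) and Marco lower (-1.13). Endothelial markers had a median of 0.017, stellate and fibroblast markers 0.096, cholangiocyte markers 0.0034, lymphocyte markers 0.0059, neutrophil markers -0.061 and erythroid markers 0.12. With ethanol, the 9 tested stellate and fibroblast markers had a median KO minus WT difference of 0.54 (camera adjusted p = 0.052), with 9 above 0 in batch 1 (median 0.5) and 7 in batch 2 (0.59). Single members were called, among them Dcn of fibroblasts (1.43 ± 0.17), Sox9 of cholangiocytes (1.56 ± 0.091) and Mmp9 of neutrophils (1.34 ± 0.16). Pericentral hepatocyte markers were higher in 3 and lower in 0 of 12 cases, and periportal markers lower in 4 and higher in 1 of 9.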

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

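The tests of the NF-kB genes, of the label conflict and of the ethanol difference between KO and WT were chosen after those results had been seen, and the counts of other sample splits were planned before.

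A difference in the ethanol effect between KO and WT, tested by limma's interaction, picked out 1061 probe sets, Tgm2 (0.802) and the medians of 2 gene lists, NF-kB and chemokines (-0.4) and amino acid, urea and gluconeogenesis genes (0.3). The genes with a more positive change in KO were Tcl1b3 (2.86), Ctse (2.79), E2f5 (2.19), Faim2 (2.19), Klf3 (2.12), Cnnm4 (2.02), Ccdc180 (1.94), 4931429L15Rik (1.93), Zfp618 (1.79) and Habp2 (1.76). Those with a more negative change were Serpinb2 (-2.4), Il23a (-2.28), Cxcl3 (-2.1), Irak1 (-1.87), Nos2 (-1.87), Mxd1 (-1.83), Ackr3 (-1.77), Vcam1 (-1.73), Swt1 (-1.49) and Sephs2 (-1.44). The Tgm2 value comes from a probe set at the top of the measured range in WT. A group mean below the offset of 16 enters the differences of Ctse, Serpinb2, Nos2, Il23a, Mxd1, Faim2 and Zfp618, so their sizes depend on the offset.

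For the ethanol difference, with 4394 calls in KO and 1105 in WT, the hybridisation batch as a term left a ratio of 2.68 (3.98 without the term). Leaving out 1 array under that term gave 1.4 (without ethanol KO A) to 10.7, so a cause in the batch stays open. In batch 2 alone more probe sets were also called in KO than in WT, but most of its groups hold 1 array. The groups compared alone gave 1511 calls in WT and 2441 in KO. This ratio of 1.62, without the term, does not bear on the batch. It bears on the spread that the main fit shares across groups. Arrays A and B differed with an SD of 0.503 in ethanol KO and of 0.315 to 0.327 in the other groups. Sharing 1 spread can raise the KO count and lower the WT count, so unequal spread stays open as part of the 3.98. Dim untreated KO arrays stay open. The A pair of KO, both dim, and the B pair correlated at 0.503 across 19814 probe sets, with ethanol KO A in another batch. Each pair subtracts a dim untreated KO array, and these 2 arrays correlated at 0.986. A distortion that they share would therefore also give a positive correlation, so this test cannot decide. RNA integrity stays open: called interactions had a median share of 0.17 (0.13 to 0.21) on a gene's brightest probe set, but these probe sets were selected by their call, and with 1 probe set per gene 5.74% were called against 5.35% of all probe sets and the ratio was 5.34. A response that depends on transglutaminase 2 stays open as untested.

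For the NF-kB and chemokine genes higher in KO, dim arrays are argued against by the bright pair, ethanol KO B minus ethanol WT B, with a median of 1.79 (1.28 to 2.86, 19 genes). The pair holds 1 array of each genotype. Intervals here are bootstrap intervals over the genes of a list and do not measure the spread between samples. The same 1.79 is the lower of the 2 within-batch medians (the other is 2.2, 1.46 to 2.96), against an effect of the inferred batches. Macrophages in the KO cultures would bring all their abundant transcripts, and the 17 markers had a median of -0.0673 (-0.29 to 0.286), although Cd68 was 1.56 higher. Such markers were measured in both genotypes, with Lyz2 at a mean log2 value of 7.19 in WT and 7.08 in KO. They bear on the number of macrophages and not on their state, which was not tested. Stellate cells and fibroblasts stay open: with ethanol their 9 tested markers had a median of 0.545 (-0.0131 to 1.05), which decides neither way, although it was 0.026 without ethanol. A difference between the genotypes in hepatocytes stays open as well, and differences in the isolation or stress of the cultures and in genetic background were not tested.

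For the conflict in the labels, the log2 ethanol change of WT pair A correlated with that of WT pair B at 0.531 (0.475 over the brightest probe set of each of 10741 genes), which argues against ethanol WT B being an untreated culture. The same test in KO gave 0.503 between pairs A and B. Both KO pairs subtract a dim untreated array, which can raise this value, so it does not decide whether ethanol KO B was untreated. The 178 probe sets called in WT with at least a 2-fold change included 160 lower ones. Their signs recurred in 64% of cases in KO pair B and 60.7% in KO pair A. The share without an ethanol effect was not computed, so these values do not decide either. Ethanol KO B correlated more with untreated KO A and B (0.973 and 0.972) than with ethanol KO A (0.967), an array of another batch. Correlations across genotypes were 0.212 for KO pair B and 0.146 for KO pair A, too low in both to decide. The Pcx ratio moved alike in both pairs of each genotype, and part of the 0.531 and 0.503 may come from RNA quality.

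The 8 arrays can be split into 4 and 4 in 35 ways, the real split included. For genotype, 1 split, the real one, gave as many calls in a 2-group model (5044, highest other 6). The splits treat the 8 arrays as independent, which the labels do not state, so they cannot exclude a chance difference between animals or cultures. Every other split also leaves genotype differences in the residual spread, which keeps its count low. For ethanol without a genotype term, 2 splits gave as many calls as the real 6, the other being the genotype split with 5044, a structure of the samples, so chance cannot be excluded in that model. With genotype as a term and 2 WT and 2 KO arrays on each side, the real split gave 1836 calls and the highest other 15, and 1 of 18 splits, the real one, gave as many, too few splits for a share under 0.05.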

How the results depend on the processing

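Trimmed-mean scaling, probe sets with a missing value, both batch settings and the dim arrays were chosen after the data were seen. Of the counts, the correlation and Tgm2, 163 values stayed and 55 moved. Staying meant a total count within 1.5 times, a correlation of the same sign within 0.1, or a Tgm2 difference of the same sign and call. The balance of higher and lower calls was not part of this rule. It shifted in some counts that stayed, as given below for keeping probe sets with a missing value. Of list results 944 stayed, 146 lost their call and 1 reversed. The reversed one was the hepatocyte identity list for ethanol averaged over genotypes, at -0.0665 (camera adjusted p = 0.84) with trimmed-mean scaling. Only lists already called entered, so none could gain a call. The 48 results with 1 probe set per gene could not change, since camera was always run on 1 probe set per gene. With an estimated correlation 39 list calls ended and 9 stayed. Of named-gene results 2972 stayed, 255 lost their call, 18 gained it and 0 reversed. Planned quantile normalisation coincided with the values reported, and camera could not be run with missing values.

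Fewer probe sets or arrays enter some of these settings; for the others the cause was not tested. No filter gave 715 for ethanol in WT and 663 for the interaction. A variance prior without a trend gave 286 (WT), 2682 (KO), 85 (interaction) and 2489 (ethanol averaged). With 1 probe set per gene, genes counted were 523 (WT), 2791 (KO), 4078 (KO against WT untreated), 3333 (with ethanol), 617 (interaction, 62.9% positive), 2546 (ethanol averaged) and 4916 (genotype averaged). The KO groups alone gave 2441. Leaving out both B ethanol arrays gave 7351 (KO) and 3261 (interaction). Counting them as untreated gave 0 (WT), 380 (KO), 1367 (KO against WT with ethanol), 0 (interaction), 2 (ethanol averaged) and 5070 (genotype averaged). Batch 2 alone gave 650 (WT) and 684 (interaction). Keeping probe sets with a missing value left 8.97% of 981 WT calls higher, 63.8% of 4924 calls between KO and WT with ethanol, 85.2% of 815 interaction calls and 34.1% of 3198 averaged ethanol calls.

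Leaving out 1 array in turn, where the lone array left is assumed to vary like the other groups, gave 284 to 2088 (ethanol in WT), 1642 to 7479 (in KO), 3972 to 8130 (KO against WT untreated), 3306 to 7524 (with ethanol), 199 to 4380 (interaction), 2213 to 6550 (ethanol averaged) and 6821 to 9481 (genotype averaged). The correlation of the ethanol changes ran from 0.122 to 0.267 and Tgm2 from -5.45 to -5.41 without and -4.71 to -4.55 with ethanol. The letters were not taken to pair the arrays, because the labels do not say what A or B share. Differences of A minus B correlated at only 0.022 to 0.031 with untreated KO. Among the 3 groups whose A array lies in batch 1 they correlated at 0.3, 0.26 and 0.2, so A and B share something there. With the letter as a replicate block the counts were 1169, 4923, 6803, 6157, 1241, 4331 and 8740, none of them moved by over 1.5 times. The number of arrays limits the precision.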

Other observations

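The test of genes near Tgm2 was chosen before its result was seen, and the gene groups named first were picked afterwards. Single genes of further lists differed between KO and WT in untreated cells, although camera called none of the lists named here. Cholesterol synthesis genes were lower in 9 and higher in 3 of 19 cases in untreated KO (10 and 3 adjusted over the list alone), with Hmgcs1 at -0.762 ± 0.063 and Cyp51 at -0.723 ± 0.071 (limma, n = 2 arrays per group), and camera gave 0.13. Mitochondrial respiratory chain genes were lower in 14 and higher in 2 of 30 cases (14 and 2 adjusted over the list alone), with Ndufv1 at -0.657 ± 0.066 and Ndufb8 at -0.654 ± 0.067, and camera gave 0.054. NRF2 and glutathione genes were lower in 15 and higher in 5 of 26 cases (15 and 5 adjusted over the list alone), with Gstm3 at -1.01 ± 0.069 and Hmox1 at 0.904 ± 0.077, and camera gave 0.054. Circadian clock genes were higher in 6 and lower in 1 of 16 cases (6 and 1 adjusted over the list alone), with Nr1d1 at 1.61 ± 0.25, and camera gave 0.062. The hepatocyte transcription factor genes Hnf4a (-1.36 ± 0.098) and Foxa2 (-2.33 ± 0.19) were lower in untreated KO, as was Ahsg (-1.34 ± 0.07), while the list of hepatocyte identity and plasma proteins had 7 lower and 2 higher of 22 (7 and 2 adjusted over the list alone), and camera gave 0.39.

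A segment of DNA from the 129SVJ strain around the targeted gene could raise the number of genotype differences near Tgm2 on chromosome 2. By gene order in GRCm38.p6, 2 of the 50 nearest tested genes were called with a log2 difference of at least 1, Sgk2 (-1.73) and Hnf4a (-1.22), against a median of 3 and a 95th percentile of 6 over 9710 windows of the same size. This argues against a cluster of such differences around Tgm2, and differences of strain elsewhere in the genome were not tested.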
